A study of Mus musculus with 3 samples.

How the data were processed

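Single-cell RNA was measured in pancreatic islets of male C57Bl6/J mice, retired breeders aged 7 to 8 months, with the droplet-based 10x Genomics 3' chemistry, per the labels' protocols. There were 3 libraries, 1 per group: mice whose pumps held no S961 (control), mice whose pumps delivered S961, an antagonist of the insulin receptor, at a labelled dose of 20 nM per week for 2 weeks (S961), and mice given the same labelled S961 course whose pumps had then been removed (recovered). The labels do not state how long recovery lasted or how many mice gave each library. Isolated islets were kept in culture overnight and dissociated with TrypLE before loading.

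The deposited values are counts: each entry is the number of unique molecular identifiers (UMIs) of 1 gene in 1 barcode, and every value tested was a whole number. The submitters' processing notes name Cell Ranger, with no version, and the mouse build mm10. The deposited table held 31053 genes and 24590 barcodes, and each barcode was assigned to its library by the suffix that the labels give. No barcode held under 500 UMIs, so the table had already been filtered on depth. Gene symbols were matched to GENCODE M21, and 30464 had an entry, from which coordinates on GRCm38/mm10 were taken. Ddit3 has a duplicated symbol there and is given without coordinates.

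Barcodes with at least 500 detected genes and at most 20% mitochondrial UMIs were kept. Doublets were called with Scrublet in each library (expected rate 0.06), as implemented in scanpy 1.11.5, and left out. It called 77 of 3507 cells in the S961 library, 24 of 3537 in the recovered library and 3 of 4270 in the control library. Doublets therefore remained nearly unremoved in control, and many may have remained in recovered, where 0.679% were called. Cells were scaled to a total of 10000, log-transformed, reduced to 2000 variable genes and 30 principal components, joined to 15 neighbours and clustered with leidenalg 0.10.2 at resolution 0.5, without batch integration. The 17 clusters were named from 14 marker sets written before the data were examined, and classes are called "-like" for that reason. A pair of naming rules was set after the clusters had been seen. Clusters with a processed pseudogene among their 20 leading genes were kept apart as pseudogene-led (2 clusters). Clusters with a low median UMI count and fewer than 2 of their own markers among the 10 leading genes were left unnamed. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

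UMIs were summed over the cells of a class in each library and scaled to the class total to give the level of a gene in CPM. Each comparison gives both CPM values and their log2 ratio with an exact conditional binomial (Clopper-Pearson) 95% interval. Shares of cells carry exact Clopper-Pearson 95% intervals, except that for a count of 0 the limit given is 3 counts of the total, and CPM values drawn in a plot carry exact Poisson 95% intervals. All intervals cover counting error only. With 1 library per group there were no replicates, so no test across mice was possible, no p-value was computed, and cells were not treated as replicates. A count of 0 was set to 3 UMIs for a ratio, which is then a bound.

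The text covers 17 gene lists written before the data were examined: beta-cell identity, dedifferentiation and disallowed genes, cell cycle, senescence regulators and markers, senescence-associated secretory (SASP) cytokines, SASP matrix and growth factors, unfolded protein response, ATF4 amino acid response, immediate early and heat shock, secretory granule, mitochondrial respiration, glycolysis, glucose-responsive ChREBP-linked genes, cholesterol synthesis, FoxO and insulin receptor signalling, interferon response, and oxidative stress defence. A member was measured if it held at least 50 UMIs over the 2 libraries compared, and was counted as higher or lower at a ratio of at least 1.25-fold. A list was summarised by its median log2 ratio, an interval from 1000 Poisson resamples of the counts, and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. A list outside the lowest and highest 2.5% is said to stand apart, and any other to lie within the random lists. The percentile describes these libraries and is not a test of the conditions.

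Named genes were chosen by a rule written before the data were examined. They were the 10 highest and 10 lowest ratios, ranked by the interval bound nearest to 0, among genes with at least 100 UMIs over the 2 libraries and at least 20 CPM in the higher one. Mitochondrial, ribosomal protein and unnamed gene models were excluded, as were markers of other cell types. Genes below 10% of their CPM in another class were passed over as possible background: Sox4 and Nupr1 among the higher genes of S961 over control, and Hilpda among the lower genes of recovered over control. In addition, 21 key genes were always given, and 5 genes each way in other classes with at least 50 cells in both libraries. The examples of a list are among its members with the largest ratios.

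The share of cells with a UMI for a marker was taken after thinning every cell to 2000 UMIs. To allow for RNA of other cells in the S961 dedifferentiation list, the profile of each other class was taken off the S961 beta-like counts, at the share that its markers reached there (Msln for pseudogene-led cells), with nothing taken off control. This was added after seeing the data and takes off too much where beta cells make a marker themselves. For the recovered library's position, S961 beta-like cells were split at random into 2 equal sets. The 100 highest and 100 lowest genes against control were chosen in one set and measured in the other.

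The interval and list calculations were tested on simulated counts drawn from each comparison's means. Intervals covered the true ratio for 95.4% of 10642 genes in S961 against control, 95.3% of 10706 in recovered against S961 and 95.9% of 10652 in recovered against control. A list of 30 unchanged genes landed at percentile 69.5, 68.9 and 98.3 in those simulations, so an unchanged list can land near the upper end.

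The alternatives planned in advance were scaling without hormone and mitochondrial genes, median-of-ratios size factors, the mean of each cell's own CPM, cells thinned to one depth, a strict filter (at least 1000 genes and at most 10% mitochondrial UMIs), no filter on cells, doublets kept, Leiden resolution 1, a member minimum of 200 UMIs, and unthinned shares. Others were added after seeing the data: leaving out the beta-like cluster led by stress genes, keeping only beta-like cells with 4 to 7% mitochondrial UMIs, shares among named cells only, and leaving out stellate-like cells in which at least 50% of the Ftl1 and Ftl1-ps1 UMIs were Ftl1-ps1.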

Results

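Islet cells of 3 libraries were sequenced, 1 each from control mice, mice given the insulin receptor antagonist S961, and recovered mice. The control library held 38265969 UMIs over 10880 barcodes, the S961 library 47651767 over 5905 and the recovered library 40102058 over 7805. After filtering and doublet removal, 4267 control, 3430 S961 and 3513 recovered cells were analysed, with medians of 6501, 9944 and 8577 UMIs per cell. The groups had no replicates, so every difference is one between libraries, and all intervals cover counting error only.

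The first question was which cell types each library held. Beta-like cells, which make insulin, formed 68.7% (95% interval 67.3 to 70.1) of the control cells, 43.4% (41.7 to 45.1) of the S961 cells and 58.8% (57.1 to 60.4) of the recovered cells. The S961 library was richer in glucagon-producing alpha-like cells (13.4%, against 7.45% in control and 7.94% in recovered), in endothelial-like cells (6.27% against 3.66% and 2.31%) and in stellate-like or fibroblast-like cells (6.03% against 2.20% and 1.45%). Somatostatin-producing delta-like cells made up 8.51% of control, 10.2% of S961 and 6.60% of recovered cells. Macrophage-like cells were 0.539%, 2.42% and 0.512%, and acinar-like cells 0.117%, 2.74% and 0.968%, in the same order. Lymphocytes were most frequent in the recovered library, where 4.04% (3.42 to 4.75) of cells were T-like or NK-like and 1.82% (1.41 to 2.32) were B-like. The S961 library held 0.875% and 0.671% of these cells and the control library 0.0703% and 0.0234%. Ductal-like cells numbered 7 in control, 18 in S961 and 20 in recovered. No cluster matched the PP, epsilon, Schwann or red blood cell markers.

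These shares depended on the filter on cells, which set both a minimum of genes and a maximum of mitochondrial UMIs. The median mitochondrial share per barcode was 26.4% in control, 5.82% in S961 and 23.1% in recovered, and 39.2%, 59.4% and 45.3% of barcodes passed. With no filter on cells, the beta-like share was 31.7% in control, 31.5% in S961 and 29.5% in recovered, so the order of the libraries was not kept. In that setting a cluster took a class only if at least 30% of its barcodes had been analysed under the filter. Clusters made up mostly of removed barcodes were thus left unnamed, so these shares cannot show which cell types the filter removed. Cells of the pseudogene-led clusters, kept out of every class after they had been seen, made up 7.41% of control, 9.10% of S961 and 10.7% of recovered cells, and unnamed cells 1.15%, 4.40% and 4.36%.

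**Figure D1:**
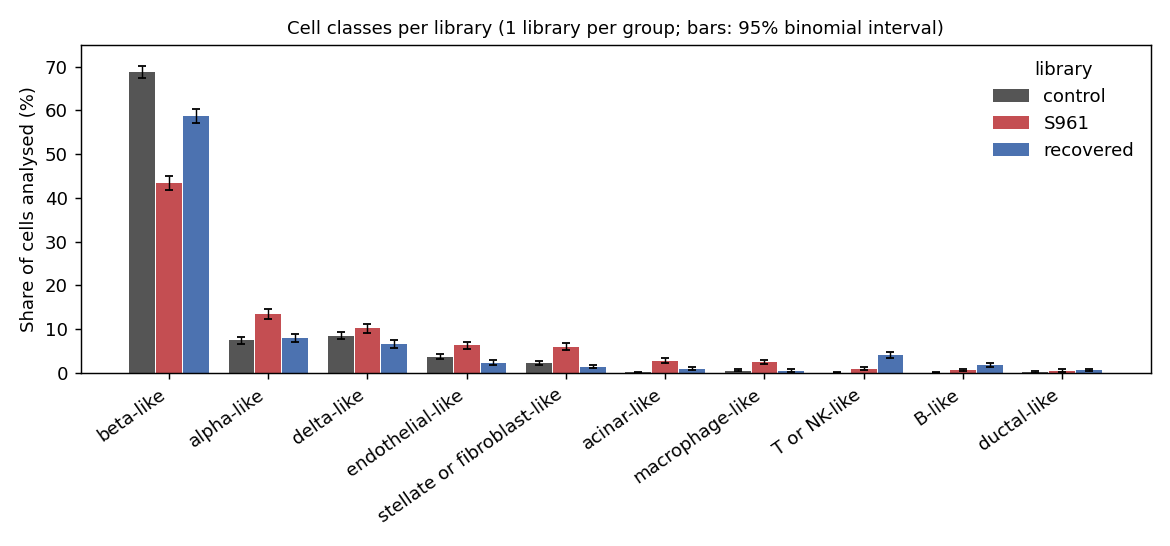
Share of analysed cells (percent, vertical axis) in each cell class for the control, S961 and recovered libraries, with bars for the exact binomial 95% interval. Beta-like cells formed 68.7%, 43.4% and 58.8% of the cells.

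The main comparison was how beta-like cells differed under insulin receptor blockade, between the S961 library (1488 cells, 21576934 UMIs) and the control library (2932 cells, 22627055 UMIs). Several genes of mature beta cells were lower. Mafa, a transcription factor that activates the insulin genes, was at 125 CPM in S961 against 353 in control, a log2 ratio of −1.50 (−1.57 to −1.44). Slc2a2, the glucose transporter of rodent beta cells, was at 40.6 against 97.1 CPM (−1.26, −1.37 to −1.14). Trpm5, a cation channel that supports insulin release, was at 23.9 against 81.9 CPM (−1.78, −1.92 to −1.64). Cdkn1a, which encodes the cell-cycle inhibitor p21, was 2.30-fold higher (2.17 to 2.43), at 171 against 74.5 CPM. Aldh1a3, a retinaldehyde dehydrogenase used as a mark of dedifferentiated beta cells, was 2.46-fold higher (2.16 to 2.81), at 36.1 against 14.7 CPM.

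The highest ratio among the named genes was that of Gpx3, a secreted glutathione peroxidase, at 237 CPM against 12.2 (4.28, 4.11 to 4.47). Others higher in S961 were the linker histone gene Hist1h1e (1.92), the fructose bisphosphatase Fbp2 (1.80), the cholesterol carrier Star (1.78), the stress-induced cytokine Gdf15 (1.17, at 30.6 against 13.7 CPM) and the thyroxine carrier Serpina7 (1.03). The granule proteins Scg2 and Chgb each had a log2 ratio of 1.06, with Scg2 at 4757 against 2280 CPM. Among the lower genes, the metallothioneins Mt2 (−1.76) and Mt1 (−1.24), which bind metal ions, were joined by the crystallin Crybb3 (−1.68), lipoprotein lipase Lpl (−1.15), Fam151a (−1.15), the phosphatase inhibitor Ppp1r1a (−1.11) and the tubulin Tuba1b (−1.15). Mt2 and Mt1 lead the stress-led beta-like cluster, which held 17.8% of control, 6.65% of S961 and 12.7% of recovered beta-like cells, and without it they were at −1.60 and −1.13. Hormone transcripts differed little, at 0.02 for Ins1, 0.15 for Ins2 and −0.02 for Iapp.

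Mafa is ENSMUSG00000047591.5 (chromosome 15, 75745490 to 75748228), Slc2a2 ENSMUSG00000027690.13 (chromosome 3, 28697903 to 28731359) and Trpm5 ENSMUSG00000009246.14 (chromosome 7, 143069153 to 143094642). Cdkn1a is ENSMUSG00000023067.14 (chromosome 17, 29090976 to 29100727), Aldh1a3 ENSMUSG00000015134.15 (chromosome 7, 66390890 to 66427517) and Gpx3 ENSMUSG00000018339.11 (chromosome 11, 54902453 to 54910377), all on GRCm38/mm10.

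Of 26 measured beta-cell identity genes, 10 were lower in S961, 2 were higher and 14 were neither, with a median log2 ratio of −0.20 (−0.25 to −0.18) at percentile 0.93 of the random lists. Beside Mafa, Slc2a2 and Trpm5, the lower members included the granule tether Sytl4 (−1.06), the incretin receptor Gipr (−0.96) and the transcription factor Pdx1 (−0.60, −0.69 to −0.51). Nkx6-1 (−0.22) and Ucn3 (−0.18) were neither. The list's median did not stand apart among cells with 4 to 7% mitochondrial UMIs (−0.13, percentile 18.0) or under the strict filter (−0.16, percentile 5.32). Of 12 measured dedifferentiation and disallowed genes, 8 were higher, 1 was lower and 3 were neither, with a median of 1.16 (0.88 to 1.24), above all 10000 random lists. Members higher were the peptide hormones Gast (3.33, with 125 UMIs against 13) and Cck (1.68), the progenitor factor Neurog3 (1.30) and the vitamin D carrier Gc (1.53), with Vim at 1.72. Gc is also an alpha-cell marker, and alpha markers summed to 2227 CPM in S961 beta-like cells against 1123 in control. Stellate markers summed to 3.52 against 0.707 CPM and acinar markers to 242 against 74.3 CPM, so RNA of other cells was not excluded for Vim, which lay at under 10% of its CPM in another class. With the RNA of other classes taken off the S961 counts, the list's median was 0.56 (0.41 to 0.65), and Neurog3 was at 1.27. The list was also higher in S961 in alpha-like (7 of 9 members, median 0.59), endothelial-like (7 of 9, 0.61) and stellate-like cells (9 of 13, 0.68, but 0.58 at percentile 96.4 without cells led by Ftl1-ps1), but not in delta-like cells (2 of 7 higher and 2 lower, percentile 21.5).

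The senescence list had 9 of 27 measured members higher, 2 lower and 16 neither, with a median of 0.15 (0.09 to 0.22) at percentile 99.6. Its higher members included the p53 target Phlda3 (1.14), the receptor decoy Bambi (0.72), the lysosomal galactosidase Glb1 (0.68, 0.49 to 0.87) and Cdkn1b (0.67). Cdkn2a, which encodes p16, held 14 UMIs in control and 18 in S961 (0.43, −0.66 to 1.55), so no difference was detectable at this depth, and the ratio was −0.64 among cells with 4 to 7% mitochondrial UMIs. Cdkn2b was at 0.15 (−0.10 to 0.39). Of 7 measured SASP cytokine genes, none was higher, 5 were lower and 2 were neither, with a median of −0.46 (−0.66 to −0.32) at percentile 0.06. The chemokine Cxcl16 (−1.22), interleukin Il1b (−0.62) and the decoy receptor Tnfrsf11b (−0.61) were among the lower ones. Without the beta-like cluster led by the stress genes Hspa1a, Hspa1b, Mt2 and Ddit3, that median was −0.23 at percentile 5.55. The SASP matrix and growth factor list had 6 of 15 members higher, 4 lower and 5 neither (median 0.22, −0.01 to 0.31, percentile 98.3), with Igfbp3 at 1.44 and Timp2 at 0.90 against Spp1 at −0.67 and Ctsb at −0.63. With a minimum of 200 UMIs per member its median was 0.02 at percentile 71.3.

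Genes of the unfolded protein response were lower: 17 of 30 were lower, 1 was higher and 12 were neither, with a median of −0.36 (−0.40 to −0.32), below all 10000 random lists. Examples are the chaperones Calr (−0.72), Sdf2l1 (−0.72) and Hyou1 (−0.71), and the main chaperone Hspa5 at −0.44 (−0.47 to −0.41). The list was also on the lower side in alpha-like (−0.06, percentile 0.45), delta-like (−0.18), endothelial-like (−0.26) and stellate-like cells (−0.16, percentile 0.01). Beta-cell RNA was lower in S961 than in control in these classes, and beta-like cells held Hspa5 at 1278 CPM in control. Insulin genes took 5.74% of endothelial-like UMIs in control and 0.788% in S961. The part of beta-cell RNA in these lower values was not measured. The stress factor Ddit3 was at −0.61, but at −0.07 without the stress-led cluster. Cholesterol synthesis genes were higher in 11 of 24 and lower in none, with 13 neither and a median of 0.27 (0.17 to 0.34), above all 10000 random lists. They included Idi1 (0.66) and Cyp51 (0.60). In oxidative stress defence, 6 of 24 were higher, 3 lower and 15 neither (median 0.15, 0.09 to 0.17, percentile 99.95). Prdx4 (0.74) and Txnrd1 (0.63) were among the higher ones, and the median was 0.04 at percentile 93.4 among cells with 4 to 7% mitochondrial UMIs.

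The secretory granule list had 9 of 25 members higher, 4 lower and 12 neither (median 0.12, 0.05 to 0.18, percentile 99.8), with the processing enzymes Pam (0.74) and Cpe (0.56) against Sytl4 (−1.06) and Gad1 (−0.73). It lay within the random lists with the mean of each cell's CPM (−0.07, percentile 64.2) and with thinned cells (−0.01, percentile 83.2), where the median of all genes had shifted by −0.10 and −0.07. Among nuclear-encoded respiratory genes, 6 of 41 were lower, 1 was higher and 34 were neither (median −0.21, −0.23 to −0.18, percentile 0.145), with Uqcrb at −0.57 and Ndufa1 at 0.52. With the mean of each cell's CPM the median was −0.12 at percentile 30.4. In glycolysis, 3 of 16 were lower, 1 was higher and 12 were neither (median −0.22, −0.25 to −0.19, percentile 1.38), with the transporter Slc2a1 at −0.99 and Ldha at −0.40. Without the stress-led cluster that median was −0.10 at percentile 28.8. ChREBP-linked genes were higher in 5 of 14, lower in 2 and neither in 7 (median 0.14, 0.02 to 0.25, percentile 98.0), with Thrsp at 1.07, the glucose-responsive Txnip at 0.87 and Scd2 at −0.72. With the mean of each cell's CPM they lay within the random lists (−0.04, percentile 78.7).

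Lists whose medians lay within the random lists were cell cycle (5 of 16 higher, 4 lower, median −0.02, percentile 47.2), ATF4 targets (5 of 26 higher, 1 lower, 0.06, percentile 94.4), immediate early and heat shock genes (5 of 20 higher, 4 lower, 0.08, percentile 96.9), FoxO and insulin receptor signalling (2 of 20 higher, 3 lower, −0.00, percentile 63.9) and interferon response (2 of 26 higher, 5 lower, −0.09, percentile 12.6). Examples are Stmn1 (1.31) for cell cycle, Slc7a3 (0.88) for ATF4 targets, Fosb (0.85) for early genes, Bcl6 (−0.76) for FoxO and B2m (−1.08) for interferon. The insulin receptor Insr was at 0.20 (0.00 to 0.40), Irs2 at 0.18 (0.03 to 0.33) and the related receptor Igf1r at −0.50 (−0.54 to −0.45, 262 against 369 CPM). The stress factor Atf3 was at 0.12 (−0.28 to 0.52), and the proliferation marker Mki67 had 10 UMIs in control and 18 in S961 (0.92, −0.28 to 2.19), a ratio of −0.02 with thinned cells and 2.56 under the strict filter.

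**Figure D2:**
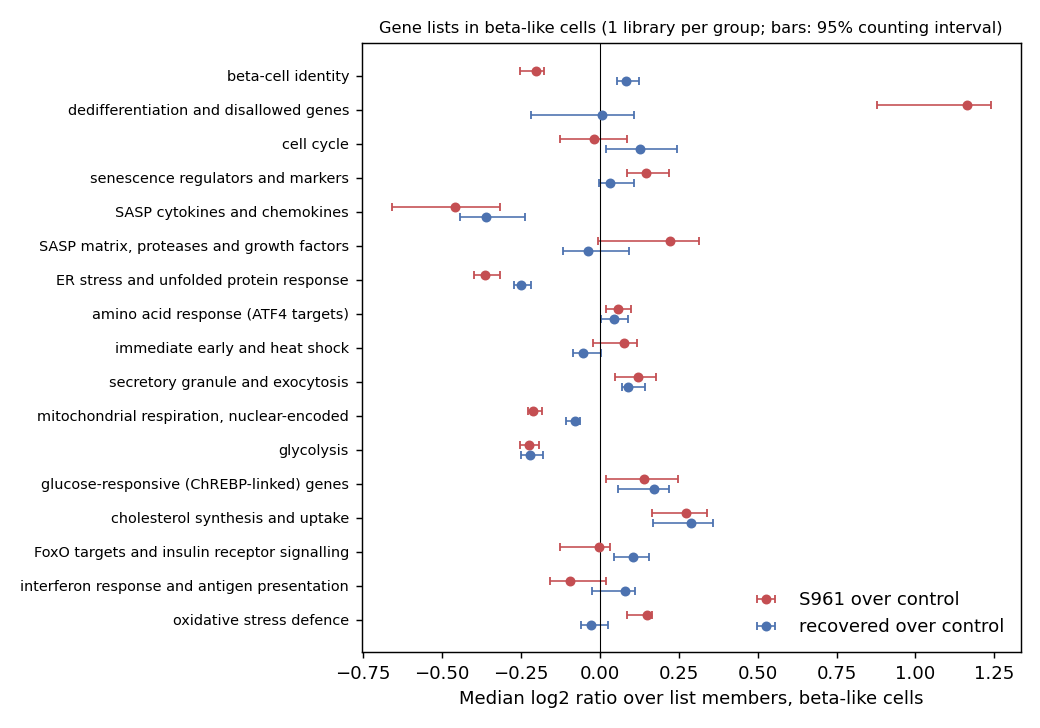
Median log2 ratio of each gene list in beta-like cells (horizontal axis) for S961 over control and recovered over control, with bars for the 95% counting interval. The dedifferentiation list lay at 1.16 for S961 over control and at 0.01 for recovered over control.

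At 2000 UMIs per cell, 22.8% (20.6 to 25.1) of 1412 S961 beta-like cells held a Cdkn1a UMI, against 12.9% (11.7 to 14.2) of 2786 control and 12.8% (11.4 to 14.4) of 2018 recovered cells. In all other named classes the shares were 26.5%, 20.6% and 19.3%, so beta-like cells were at or below them in each library. Unthinned, the beta-like shares were 57.9%, 31.1% and 41.4% at median depths of 13948.5, 7481.5 and 10318 UMIs, and those of the other classes 50.9%, 32.9% and 29.8% at 9060, 4394 and 5782 UMIs. Aldh1a3 was in 5.24% of S961, 2.62% of control and 0.991% of recovered beta-like cells, against 1.34%, 1.37% and 1.19% in the other classes, and unthinned in 18.8%, 8.36% and 4.55%. Igf1r was in 28.7% of S961, 40.9% of control and 38.9% of recovered beta-like cells (other classes 8.63%, 15.3% and 10.3%; unthinned 61.2%, 73.7% and 78.2%). Ddit3 was in 18.2%, 27.0% and 23.2% in that order (other classes 12.4%, 14.1% and 11.0%; unthinned 52.8%, 52.8% and 58.3%). Cdkn2b, at 2.48%, 2.08% and 3.47%, lay below the other classes, at 5.02%, 5.04% and 4.76% (unthinned beta-like shares 15.9%, 8.42% and 14.3%). Cdkn2a was in 0 of 1412 S961 cells, which allows a share of up to 0.212%, in 0.108% of control and in 0.545% of recovered cells. The other classes held it in 0 of 1414 (up to 0.212%), 0.115% and 0.132%, and the unthinned beta-like shares were 1.21%, 0.443% and 1.79%. Mki67 was in 1 of 1412 S961, 2 of 2786 control and 2 of 2018 recovered beta-like cells and Top2a in 1, 2 and 0 (up to 0.149%), all below the other classes in S961 and recovered (0.636% and 1.19% for Mki67, 0.919% and 1.32% for Top2a). Control cells of the other classes held Mki67 in 0 of 873 (up to 0.344%) and Top2a in 0.458%. Unthinned, Mki67 was in 1.21% of S961, 0.341% of control and 0.436% of recovered beta-like cells, and Top2a in 0.403%, 0.171% and 0.242%.

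Outside beta-like cells, the amount of insulin RNA differed between libraries. Endothelial-like cells held a median of 108 Ins1 and Ins2 UMIs in control, 9 in S961 and 72 in recovered, and alpha-like cells 112.5, 12 and 77. Genes abundant in beta cells are therefore left aside in these classes, including the lower Scg3, Pcsk2, Chgb, Scg5, Crybb3, Prss53 and Ero1lb ratios of S961 over control. Insulin genes took 10.4% of stellate-like UMIs in control, 1.41% in S961 and 2.79% in recovered. In delta-like cells they took 7.79%, 0.866% and 7.67%. Recovered delta-like cells held a median of 84.5 insulin UMIs at a median depth of 6849 UMIs. Cells with far more insulin RNA than the median therefore carried much of that share. Free RNA, doublets and mixed cells were not told apart. Less beta-cell RNA raises the CPM of a class's own genes, so higher ratios of S961 over control there include a part not measured. Lower ratios of recovered over S961 in delta-like cells do likewise. Gene lists were not corrected for beta-cell RNA. In the other direction, acinar markers summed to 74.3 CPM in control beta-like cells, 242 in S961 and 213 in recovered.

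In alpha-like cells, S961 over control ratios were highest for the Rac exchange factor Prex1 (1.67), complement factor Cfi (1.59), Lars2 (1.30), the lipid chaperone Fabp5 (76.3 against 32.0 CPM) and fibrinogen Fgb (1.17). Among the lowest ratios, Mt2 (−1.43), Enho (−1.59) and Papss2 (−1.42) are genes that beta-like cells also held in quantity. Glycolysis genes were higher in 9 of 17 and lower in none (median 0.33, above all 10000 random lists), led by Ldha (0.97) and Hk1 (0.82). Cholesterol synthesis genes were higher in 11 of 23 and lower in none (0.30, percentile 99.8). In delta-like cells the immediate early and heat shock list was higher in 15 of 19 and lower in none (0.58, above all 10000 random lists), with Hspa1a at 1.23 and Dusp1 at 1.17. Other delta-like genes higher in S961 were Ogfrl1 (1.57), the growth factor Ptn (1.37), Cited1 (1.42), Hist1h1e (1.41) and Jun (0.90).

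In endothelial-like cells the apelin receptor Aplnr was at 143 CPM in S961 against 10.9 in control (3.72, 2.65 to 5.05). The lipase inhibitor Angptl4 (2.37), Gdf15 (1.94) and neurotensin Nts (2.07) were also higher. SASP matrix genes were higher in 14 of 22 and lower in 3 (0.44, percentile 99.99), with Mmp14 at 1.61, and 3 of 6 SASP cytokine genes were higher and 1 lower (0.67, percentile 99.7), with Cx3cl1 at 1.10 and Cxcl10 at −1.22. In stellate-like or fibroblast-like cells the growth factor Btc held 445 UMIs in S961 and 2 in control (5.34, 3.48 to 8.39) and Cilp 214 and 2 (4.28, 2.41 to 7.34). Galectin Lgals3 was at 852 against 79.0 CPM (3.43). The protease Mmp3 held 125 UMIs against 0 and the lipid binder Fabp7 127 against 0, at least 7.57-fold and 7.70-fold higher at a floor of 3 UMIs. SASP cytokine genes were higher in 10 of 13 and lower in none (1.13, 0.71 to 1.58, percentile 99.98), among them the adhesion molecule Vcam1 with 72 UMIs against 1 (3.71, 1.19 to 9.03) and Cxcl12 with 67 against 2 (2.61, 0.70 to 5.68). SASP matrix genes were higher in 23 of 32 and lower in 2 (0.75, 0.64 to 0.98, above all 10000 random lists), with the growth factor Ereg at 109 UMIs against 0 (at least 2.72) and the protease Plat at 1.94. Of the stellate-like cells with at least 5 Ftl1 and Ftl1-ps1 UMIs, 14 of 83 in control, 6 of 189 in S961 and 5 of 48 in recovered were led by the pseudogene Ftl1-ps1.

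The recovered and S961 libraries were compared to ask whether beta-like cells differed once the pumps had been removed. Genes picked as extremes of S961 over control share the S961 library with this comparison, so opposite signs are favoured in advance. Mafa was at 370 CPM in recovered (2064 cells, 22394307 UMIs) against 125 in S961 (1.57, 1.51 to 1.63), Slc2a2 at 116 against 40.6 (1.52, 1.41 to 1.63) and Trpm5 at 76.8 against 23.9 (1.69, 1.54 to 1.83). Aldh1a3 was 5.15-fold lower, at 7.01 against 36.1 CPM (−2.36, −2.62 to −2.12). Cdkn1a was at 75.1 against 171 CPM (−1.19, −1.27 to −1.11) and Gpx3 at 52.2 against 237 (−2.18).

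Further genes higher in recovered were Lpl (1.55), Ppp1r1a (1.35), Fam151a (1.29), Sytl4 (1.14), the amine oxidase Maob (1.12), the axon guidance receptor Robo2 (1.06) and the granule zinc transporter Slc30a8 (1.05). Further lower genes were Fbp2 (−1.98), Serpina7 (−1.37), Gdf15 (−1.21), Hist1h1e (−1.13), the early response factor Jun (−1.09, 75.8 against 162 CPM), Chgb (−1.01) and Scg2 (−0.99). Of 26 identity genes, 13 were higher and none lower, with 13 neither and a median of 0.33 (0.29 to 0.41), above all 10000 random lists. Ucn3, a peptide of mature beta cells, was at 0.69, Pdx1 at 0.56 and Nkx6-1 at 0.41. Of 12 dedifferentiation genes, 8 were lower, 1 was higher and 3 were neither, with a median of −1.22 (−1.42 to −0.97), below all 10000 random lists. Cck (−2.13), Gast (−1.73) and Gc (−1.44) were among the lower ones. Gc is also an alpha-cell marker, and alpha markers summed to 1310 CPM in recovered beta-like cells against 2227 in S961. RNA of other cells was not taken off in this comparison.

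The senescence list had 8 of 27 members lower and 4 higher, with a median of −0.19 (−0.22 to −0.07), below all 10000 random lists, and Phlda3 at −1.66. With cells thinned to one depth it lay within the random lists (0.06, percentile 23.2), where the median of all genes had shifted by 0.07. Cdkn2a, with 39 UMIs against 18, had a ratio of 1.06 (0.22 to 1.95), and 2.12 among cells with 4 to 7% mitochondrial UMIs. Cdkn2b was at 0.15 (−0.09 to 0.38), Glb1 at −0.32 and Txnip at −0.35. Oxidative stress defence was lower in 6 of 24 and higher in 3 (−0.14, percentile 0.06), and SASP matrix genes lower in 6 of 15 and higher in 4 (−0.15, percentile 1.06), with Igfbp3 at −1.76 and Inhba at −1.34. These medians were −0.02 at percentile 4.36 with 4 to 7% mitochondrial UMIs and −0.09 at percentile 4.32 with at least 200 UMIs. Immediate early and heat shock genes were lower in 4 of 20 and higher in 1 (−0.09, percentile 1.28), but within the random lists with the mean of each cell's CPM (0.06, percentile 33.0). Respiratory genes were higher in 1 of 41 and lower in 1 (0.13, percentile 99.7), and at 0.02 (percentile 35.9) with the mean of each cell's CPM. The other lists lay within the random lists, among them SASP cytokines (0.13, percentile 77.5) and the unfolded protein response (0.09, percentile 88.0). Igf1r was at 0.29 (0.24 to 0.34), Irs2 at −0.26, Insr at −0.11 (−0.31 to 0.08), Hspa5 at 0.09, Ddit3 at 0.08, Atf3 at −0.19 (−0.60 to 0.21) and Mki67, with 9 UMIs against 18, at −1.05 (−2.39 to 0.18), or 0.48 with thinned cells and −1.69 with 4 to 7% mitochondrial UMIs. Ins1 was at −0.09, Ins2 at −0.10 and Iapp at −0.07.

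**Figure D3:**
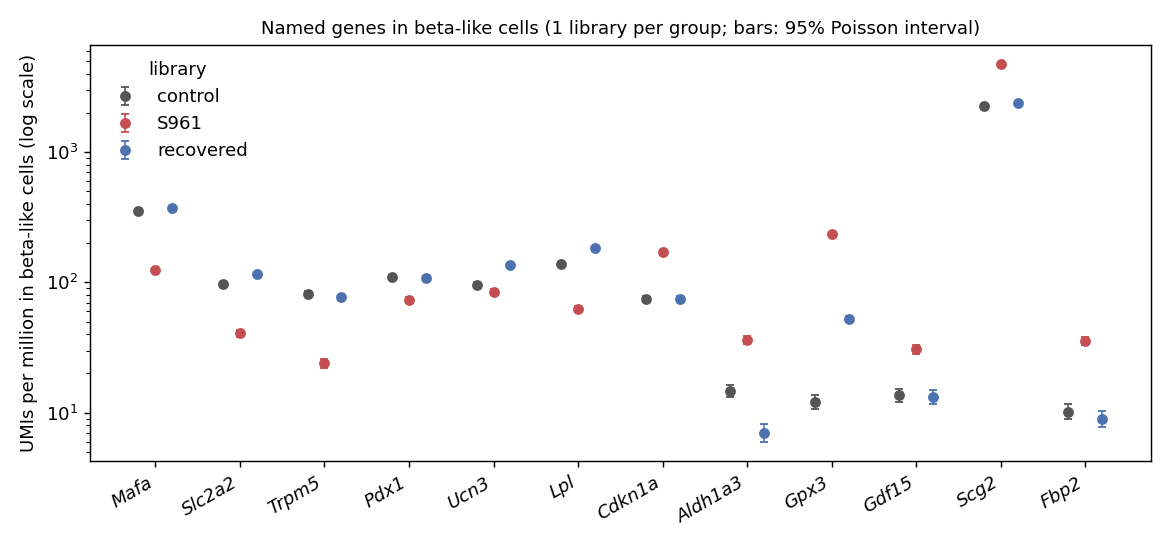
CPM in beta-like cells (vertical log axis) of 12 named genes in the control, S961 and recovered libraries, with bars for the exact Poisson 95% interval. Mafa was at 353, 125 and 370 CPM and Cdkn1a at 74.5, 171 and 75.1 CPM.

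In other classes, alpha-like cells of the recovered library had lower glycolysis genes than S961 ones (14 of 17 lower and none higher, −0.48, below all 10000 random lists), led by Ldha (−1.22), and a higher ratio for Nts (2.19). Delta-like cells had lower immediate early and heat shock genes (13 of 19 lower and none higher, −0.44, below all 10000 random lists), with Hspa1a at −2.32, and lower Cited1 (−1.50) and Ldha (−1.27). Insulin genes took 0.866% of delta-like UMIs in S961 and 7.67% in recovered. More beta-cell RNA may therefore add to lower delta-like ratios, by an amount that was not measured. Endothelial-like cells had higher Igfbp5 (4.49), carbonic anhydrase Car4 (3.08) and fibronectin Fn1 (2.59), and lower Gdf15 (−2.03) and Aplnr (−2.08). Interferon response genes were higher in 19 of 28 endothelial-like measurements and lower in 1 (0.50, above all 10000 random lists), with Ifit3 at 1.93. In alpha-like cells they were lower in 6 of 20 and higher in none (−0.19, percentile 0.65), and in delta-like cells lower in 8 of 17 and higher in none (−0.31, percentile 0.05). They were higher in 21 of 23 in the 51 recovered stellate-like cells and lower in none (1.33), with Ifit1 at 4.12. Complement C3 (4.57), the chemokine Cxcl10 (4.30) and the alarmin Il33 (3.89) were highest there, and Hspa1a (−4.48) and interleukin Il11 (−2.11) were lower. The unfolded protein response list was higher in 19 of 25 stellate-like measurements and lower in 2 (0.59, above all 10000 random lists), with Sdf2l1 at 1.60.

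The recovered and control libraries were compared to ask what remained different after the pumps were out. In beta-like cells, several genes that differed under S961 were close to control: Mafa at 0.07 (0.02 to 0.11), Pdx1 at −0.03 (−0.12 to 0.05) and Cdkn1a at 0.01 (−0.09 to 0.11). Others were not. Gpx3 was 4.30-fold higher (3.77 to 4.92), Crybb3 lower at 199 against 469 CPM (−1.24), and Mt2 (−0.97) and Mt1 (−0.90) were lower as well. Aldh1a3 was lower than in control, at 7.01 against 14.7 CPM (−1.07, −1.35 to −0.79). Ucn3 (0.51, 0.43 to 0.59) and Cdkn2a (1.49, 0.58 to 2.49, with 39 UMIs against 14) were higher. With cells thinned to one depth Cdkn2a was at 2.34, but only 11 recovered and 3 control cells then held it.

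Also higher were the insulin receptor relative Insrr (0.79), Rad51ap2 (0.82), the chromatin organiser Satb1 (0.78), Cib3 (0.75), Cryba2 (0.68), Tox3 (0.59), the peroxidase Gpx2 (0.56), the cyclin Ccnd2 (0.52, 535 against 372 CPM) and the stress-induced Nupr1 (0.50). Also lower were C2cd4a (−1.62, 18.0 against 55.0 CPM), the glucose transporter Slc2a1 (−0.93), the retrieval receptor Kdelr3 (−0.88), Dapl1 (−0.78), prodynorphin Pdyn (−0.63), the chaperone Creld2 (−0.63) and the signalling regulator Rgs4 (−0.62). Slc2a2 was at 0.26, Nkx6-1 at 0.18, Txnip at 0.51, Glb1 at 0.36, Cdkn2b at 0.29 and Igf1r at −0.21. Insr was at 0.09 (−0.11 to 0.29), Irs2 at −0.08 (−0.24 to 0.08), Atf3 at −0.07 (−0.48 to 0.34) and Mki67 at −0.14 (−1.61 to 1.32), or 0.47 with thinned cells and 1.63 under the strict filter. Hspa5 was at −0.35, Ins1 at −0.07, Ins2 at 0.05 and Iapp at −0.09. Ddit3 was at −0.53, but at −0.08 without the stress-led cluster.

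Cholesterol synthesis genes were higher in 11 of 24 and lower in none (median 0.29, 0.17 to 0.36, above all 10000 random lists). With thinned cells the median was 0.18 at percentile 96.3. The unfolded protein response was lower in 10 of 30 and higher in none (−0.25, −0.27 to −0.22), glycolysis lower in 4 of 16 and higher in 1 (−0.22, −0.25 to −0.18, Ldha −0.66), and SASP cytokines lower in 5 of 8 and higher in 1 (−0.36, −0.44 to −0.24), each below every random list. Tnfrsf11b was at −0.92, and Cxcl16 was also lower. The chemokine Ccl5 was the higher one, with 57 UMIs against 1 (5.85, 3.31 to 11.18), and it was at 635 CPM in recovered T-like or NK-like cells. Identity genes were higher in 2 of 26 and lower in none (0.08, 0.05 to 0.12, percentile 99.9), at 0.02 and percentile 81.4 among cells with 4 to 7% mitochondrial UMIs. The granule list (0.09, percentile 99.9) and ChREBP-linked genes (0.17, percentile 99.4) were also on the higher side, the latter at percentile 82.8 with the mean of each cell's CPM. The senescence list (0.03, percentile 50.3), the dedifferentiation list (0.01, percentile 23.7) and the remaining ones lay within the random lists, with Stmn1 at 0.64 for cell cycle and Isg15 at 1.27 for interferon.

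Of the 100 genes highest in one set of S961 beta-like cells over control, the median log2 ratio was 0.70 in the other set and 0.23 in the recovered library, where 85 lay on the same side of control as S961 and 73 lay nearer to control than to S961. Of the 100 lowest, the medians were −0.66 and −0.17, with 76 on the same side and 81 nearer to control. Both sets share the S961 and control libraries, so variation between libraries was not removed. The recovered ratios use the same control library as well, so lying on the same side of control is favoured in advance.

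In other classes, recovered over control, alpha-like cells had higher Nts (2.80, 103 UMIs against 12) and lower ATF4 targets (10 of 16 lower and none higher, −0.35, below all 10000 random lists). Delta-like cells had lower Ldha (−1.37), the interferon-induced Bst2 (−1.52) and glycolysis genes (8 of 15 lower and none higher, −0.40, below all 10000 random lists). Endothelial-like cells had higher Igfbp5 (2.80) and Angptl4 (2.17). Their interferon genes were higher in 17 of 23 and lower in none (0.51, above all 10000 random lists), while those of alpha-like cells were lower in 6 of 16 and higher in 2 (−0.17, percentile 0.58) and those of delta-like cells lower in 5 of 17 and higher in 1 (−0.19, percentile 0.27). Stellate-like cells, 51 against 94, had higher Apoe (5.29), C3 (5.15), Plac8 (4.45) and Il33 (3.80). Cxcl10 held 313 UMIs there against 0, at least 6.65 on the log2 scale at a floor of 3 UMIs. Their interferon genes were higher in 15 of 15 (1.81, 1.59 to 2.09) and their SASP cytokine genes in 7 of 9, with 1 lower (1.10, 0.81 to 1.76). Without the cells led by Ftl1-ps1 the SASP cytokine median was 3.64, with no interval computed. Its size thus depended strongly on which cells were counted and is not read as a larger difference.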

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

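The tests with respiratory genes, with Ftl1-ps1 in non-endocrine cells and with RNA of other classes taken off were chosen only after the result was seen, and so was the band of 4 to 7% mitochondrial UMIs, though the bound it had to meet was written before its value was known. The size and background conditions by which differences between cell types were picked out were set after a first, looser pass had listed too many.

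A list was picked out where its median lay on opposite sides in different cell types, each outside the lowest or highest 2.5% of random lists. The differences between cell types were not tested, since each rests on 1 library per group. Beta-cell RNA in the other classes also differed between libraries, and its part in the medians below was not measured. In control, S961 and recovered, insulin genes took 5.74%, 0.788% and 1.53% of endothelial-like UMIs. They took 10.4%, 1.41% and 2.79% of stellate-like and 7.79%, 0.866% and 7.67% of delta-like UMIs. SASP cytokine genes were lower in beta-like cells of S961 than of control (−0.46) but higher in endothelial-like (0.67) and stellate-like cells (1.13). Recovered over control, they were at −0.36 in beta-like and 1.10 in stellate-like cells. The dedifferentiation list, recovered over S961, was at −1.22 in beta-like, −0.43 in alpha-like and 0.87 in stellate-like cells. Immediate early and heat shock genes in that comparison were at −0.44 in delta-like and 0.34 in stellate-like cells, and glycolysis at −0.48 in alpha-like and 0.43 in stellate-like cells. The unfolded protein response, recovered over control, was at −0.36 in endothelial-like and 0.39 in stellate-like cells, where it did not stand apart (percentile 96.3) without cells led by Ftl1-ps1. Endothelial-like cells held less beta-cell RNA in recovered than in control, which may add to their lower value. Interferon genes, recovered over S961, also lay on opposite sides, at 0.50 in endothelial-like, 1.33 in stellate-like, −0.19 in alpha-like and −0.31 in delta-like cells, but the lower values were short of the size condition. Cells outside every comparison were picked out by their share against control: the pseudogene-led clusters (10.7% in recovered) and unnamed clusters (4.40% in S961 and 4.36% in recovered).

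The first pattern weighed was the pair of pseudogene-led clusters, present in all 3 libraries. In cells with at least 5 UMIs of the ferritin gene Ftl1 and its pseudogene, 752 of 776 were led by Ftl1-ps1, against 1 of 6276 beta-like cells. In control, Gapdh was at 87.3 CPM against 1399 in beta-like cells. The mitochondrial genes mt-Atp6 and mt-Cytb were there at 1764 against 14483 CPM and 4200 against 7230 CPM. A test written beforehand met its bound, with an SD of 0.944 over 77 ribosomal protein genes against 0.433 in the highest named class, but ribosomal pseudogenes lead these clusters, so it was set aside as circular. Over 34 respiratory genes, the log2 ratio to beta-like cells had an SD of 0.706 (0.551 to 0.842), against 0.538 in T-like or NK-like cells, the highest named class. That is short of the 2-fold set for cells of another species and not low enough to exclude them, so this explanation stays open. A state of mouse endocrine cells as the whole cause is argued against by the non-endocrine named cells that were led by Ftl1-ps1 and held too little insulin RNA for a doublet, 38 of 1134 or 3.35% (2.38 to 4.57), where under 1% was allowed. Before the limit on insulin RNA, those led by Ftl1-ps1 were 6.64% in control, 1.64% (0.79 to 3.00) in S961 and 4.83% in recovered. The bound was thus not cleared in S961 alone. Such cells were 25 of 320 stellate-like and 0 of 400 endothelial-like cells.

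The next pattern was the higher dedifferentiation list in S961 beta-like cells. RNA from other cell types stays open for the list as a whole: with it taken off the S961 counts the median was 0.56 (0.41 to 0.65), above 0 but not above 0.5 of its size before. The amount taken off may be too large. The profile of 18 ductal-like cells was taken off at 4.55%, though ductal markers summed to 1614 CPM in S961 beta-like cells against 1904 in control. Aldh1a3 (1.29), Neurog3 (1.27), Gast (3.33) and Cck (1.66) were hardly altered, while Vim and Ldha fell away, at a limit that exceeds what Ldha held. A test written beforehand, which kept 7 members by their S961 level (median 1.30), was set aside because that level is what it tests. Fewer damaged cells in the S961 library, as judged by mitochondrial share, is argued against by the median among cells with 4 to 7% mitochondrial UMIs. It was 1.08 (0.77 to 1.30). That band did not match depth, with 11293773 UMIs over 592 S961 cells and 10853577 over 1264 control cells. A response to insulin receptor blockade may explain the higher list, as a hypothesis found and tested on the same data. It was not shown to be particular to beta cells. The list was also higher in alpha-like (0.59) and endothelial-like cells (0.61), though not in delta-like cells (percentile 21.5). A difference between libraries unrelated to S961 stays open, because each group had 1.

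The last pattern was the larger share of T and B cells in the recovered library. Lymphoid tissue carried over as a whole is argued against by the ratio of naive to effector marker UMIs in its T-like or NK-like cells, 0.297 (0.243 to 0.361), from 133 and 448 UMIs. That ratio leans on few cells, since 103 of the effector UMIs were Gzmb in 4 cells, while the naive marker Tcf7 was in 36.6% of the 142 cells and the tissue-homing receptor Cxcr6 in 31.0%. A part carried over therefore stays open. With no filter on cells the recovered share was 3.58 times that of S961, which met the bound set against cell loss by the filter. That test could not decide, because a cluster there was named only if at least 30% of its barcodes had been analysed under the filter. Lymphocytes lost by the filter could hardly be counted: 51 were named in S961 and 241 in recovered, against 53 and 206 with the filter. Cell loss by the filter therefore stays open. Entry of lymphocytes into the islets may also explain the larger share, but recovery and library are the same split here.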

How the results depend on the processing

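Leaving out the stress-led cluster, keeping 4 to 7% mitochondrial UMIs, counting named cells only and leaving out cells led by Ftl1-ps1 were tests chosen only after the result was seen; all others were planned. No paired analysis was possible because each group had 1 library and the labels pair none.

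Of 115 gene ratios in beta-like cells, 104 kept their sign with thinned cells, 105 with the mean of each cell's CPM and 107 with 4 to 7% mitochondrial UMIs, and 58, 47 and 62 left their intervals. Those that turned were below the size at which list members count as higher or lower, or had an interval across 0. All 51 list medians stayed within their intervals when scaled without hormone and mitochondrial genes, with doublets kept and at Leiden resolution 1. With median-of-ratios factors 29 did, with the mean of each cell's CPM 26, with thinned cells 29, with the strict filter 37 and with no filter 47. Without the stress-led cluster 40 did, and among cells with 4 to 7% mitochondrial UMIs 28. Of 48 stellate-like list medians, 43 stayed within theirs without cells led by Ftl1-ps1, and 1 of 24 shares of cells with a UMI did when not thinned.

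Of 51 list medians, 42 kept their sign with the mean of each cell's CPM, 44 thinned, 42 under the strict filter and 42 with 4 to 7% mitochondrial UMIs. Among lists that stood apart from the random ones, these changed sign, and any other cause was not tested. With the mean of each cell's CPM, S961 over control, secretory granule genes were at −0.070 and ChREBP-linked genes at −0.039, and immediate early and heat shock genes, recovered over S961, at 0.061. With cells thinned to one depth, granule genes were at −0.0099 in S961 over control and the senescence list at 0.057 in recovered over S961. Each keeps its sign once the shift of the median of all genes under that setting is taken off. For S961 over control and recovered over S961, that shift was −0.10 and 0.10 with the mean of each cell's CPM. Thinned, it was −0.07 and 0.07. A scaling that all genes share moves the random lists too, yet these lists no longer stood apart from them. Their percentiles were 64.2, 78.7 and 33.0 with the mean of each cell's CPM, and 83.2 and 23.2 thinned. A shared scaling therefore does not account for the whole of each move.

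The identity list kept its direction throughout, while its size depended on the setting, and the cause was not tested. Its medians for S961 over control were −0.17 with median-of-ratios factors, −0.35 with the mean of each cell's CPM, −0.32 thinned, −0.16 under the strict filter, −0.26 without the stress-led cluster and −0.13 with 4 to 7% mitochondrial UMIs. For recovered over S961 they were 0.26, 0.48, 0.50, 0.26 and, with 4 to 7%, 0.23. For recovered over control they were 0.051 with median-of-ratios factors and 0.021 with 4 to 7%. The mean of each cell's CPM shifted the median of all genes by −0.10 for S961 over control, so part of its value is scaling.

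The senescence list for S961 over control was at 0.035 with the mean of each cell's CPM, 0.087 thinned and 0.23 with 4 to 7%. For recovered over S961 it was at −0.26 with median-of-ratios factors and −0.039 with the mean of each cell's CPM. The dedifferentiation list was at 0.86 for S961 over control with at least 200 UMIs per member, and for recovered over S961 at −0.79 with no filter and −0.96 with 4 to 7%. SASP cytokines were at −0.23 for S961 over control without the stress-led cluster. They were at −0.10 for recovered over S961 with at least 200 UMIs, and for recovered over control at −0.19 with no filter and −0.17 with 4 to 7%. The cause was not tested.

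Beta-like shares were 66.7% in control and 38.2% in S961 under the strict filter, 31.7%, 31.5% and 29.5% in control, S961 and recovered with no filter, and 61.5% in recovered with doublets kept. Among named cells only they were 75.1%, 50.2% and 69.1%. The cause was not tested.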

Other observations

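A small unnamed cluster carried Ccr7, a receptor that guides cells to lymph nodes, with the chemokine Ccl22 and the actin bundler Fscn1, genes of mature dendritic cells. It held 0 control cells, which allows up to 0.0703% of that library, 1 S961 cell and 19 recovered cells. The B-like cluster was led by antibody genes of plasma cells (Igkc, Ighm, Ighg1, Jchain and Mzb1) together with the cell-cycle genes Top2a, Mki67 and Ube2c, and 64 of its cells were in the recovered library against 1 in control and 23 in S961. Macrophage-like cells were led by Apoe, C1qb and Trem2. An unnamed cluster of low depth, with a median of 1505 UMIs, was led by nuclear RNAs (Malat1, Neat1 and Kcnq1ot1) and held 36, 131 and 127 cells in control, S961 and recovered.

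The pseudogene-led cells held RNA assigned to islet hormone genes. Whether they were mouse cells stayed open, so the levels below are of RNA assigned to mouse genes and name no mouse cell type. Ins1 was at 159443 CPM in control and Gcg at 18927 CPM in control, 24600 in S961 and 25353 in recovered. Mesothelin Msln was at 1174, 942 and 1185 CPM, against 4.64, 3.01 and 6.56 in beta-like cells. The thyrotropin-releasing hormone gene Trh was at 301, 500 and 283 CPM and the GABA enzyme Gad2 at 157, 192 and 163. Metallothioneins were lower under S961 in several classes: Mt2 at −1.43 in alpha-like cells and −2.58 in endothelial-like cells, where Mt1 was at 66.1 against 441 CPM. Beta-like cells had 1594 CPM of Mt1 in control. Insulin genes took 5.74% of the UMIs of control endothelial-like cells against 0.788% in S961. Beta-cell RNA therefore adds to that Mt1 ratio by an amount that was not measured.

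The cluster and filter tests named here with 4 to 7% mitochondrial UMIs and without the stress-led cluster were chosen only after the result was seen. The senescence list and the SASP cytokine list went opposite ways in S961 beta-like cells, with Cdkn1a and Gdf15 higher and Cxcl16 and Il1b lower. Part of the lower SASP median may come from cells with high stress genes, since it was −0.23 without the stress-led cluster. The senescence median was 0.23 with 4 to 7% mitochondrial UMIs, so a difference in mitochondrial share alone did not give its direction. That band did not match depth, with 11293773 UMIs over 592 S961 cells and 10853577 over 1264 control cells. The median was smaller at 0.087 with thinned cells and 0.035 with the mean of each cell's CPM. A part of cell quality or depth in it therefore stays open. Cdkn2a did not follow Cdkn1a, and was highest in the recovered library at 1.74 CPM, from 39 UMIs. Deeper libraries from several mice per group would be needed to read Cdkn2a.

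Gpx3 was higher than control in both other libraries. The cholesterol synthesis median of recovered over control was 0.29, and 0.18 with thinned cells, where it did not stand apart, while Mafa (0.07) and Cdkn1a (0.01) lay close to control.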
